A study of Drosophila melanogaster with 4 samples.

How the data were processed

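Chromatin from wild-type Oregon-R embryos of Drosophila melanogaster, collected at 14 to 16 h of development, was assayed by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody to histone H4, a core subunit of the nucleosome. Per the labels' protocols, embryos were crosslinked with 1.8% formaldehyde. The series held 4 libraries: 2 H4 ChIP libraries and 2 input libraries of genomic DNA. Per the labels, each input served as the control of the ChIP library with the same replicate number. The labels do not say whether the replicates came from separate embryo collections, so the spread between them may be technical.

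The deposited data were 3 lists of regions, 1 for each ChIP library and 1 combined list for the replicate set. Bowtie 0.12.7 was named in the submitters' processing notes. The genome build was FlyBase r5, per the file headers. The region caller, its threshold, its window size and the way the replicates were combined are not given in the sources used here. Each region came with a first and last base, which are other values than measurements and were taken from the deposited lists as 1-based coordinates, and with a score that the authors gave to each region. The scale and log base of the deposited score are not stated. It was above 0 in regions named as enriched and below 0 in regions named as depleted, and it was used to describe, rank, filter and compare regions within a list. Between the replicate lists it was compared only by the Pearson and Spearman correlations of paired regions. No read counts or coverage were used, so the sequencing depth of the 4 libraries is unknown and no counting interval for a region can be given. The narrowest region was 1301 bp in both replicate lists and 1001 bp in the combined list.

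Covered shares were computed per base over the 13 sequences that held at least 1 region, 140 Mb in all. The sequence named Uextra (29.0 Mb of unplaced sequence in the headers) held no region in any list and was left out of every denominator. The labels paired no value of the input libraries with a file, so the background is only present through the authors' own calls against input.

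Overlap between the replicate lists was computed in bases and tested against 100000 joint circular shifts of 1 list within each sequence, in bins of 100 bp that counted as covered when at least 50% of their bases were (one-sided permutation test). The covered share of each sequence was tested, for each replicate, against 100000 rotations of that list around the joined genome (two-sided permutation test), with Benjamini-Hochberg adjustment over the 13 sequences. A sequence was called only where both replicates passed an adjusted p of 0.05 in the same direction. These tests permute positions, not embryos, and so describe these lists. Rotations that place a long arm at nearby positions overlap, so 100000 rotations hold far fewer independent draws. On simulated data made from the 15405 region widths of replicate 1, independently placed lists had a p under 0.05 in 6% of 50 runs, evenly spread regions gave calls for 3.38% of sequences, and X or 2R thinned to 50% of its regions was called lower in 50 of 50 runs each. The simulated regions were placed at random, without the gathering of regions described below, and each simulated list was tested alone. These rates therefore do not give the error rate or the power of the sequence calls on the real lists. Scores were compared over pairs of regions that were each other's largest overlap. Intervals for ratios of covered shares came from 10000 bootstrap resamples of windows, and intervals for score differences from 2000 resamples of regions, both at 95%. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

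The tests of the report's comparisons and the rule for named regions were fixed before the data were examined, but not the windows of 1 Mb, the gaps or the tests of explanations. Named are the 10 longest and the 10 highest scoring regions of the combined list, taken from regions with at least 50% of their bases in each replicate list. 3 of the 8 planned results were not run: the overlap with annotated genes, the coverage of 14 gene lists, and base composition. The gene table at hand used Release 6 of the assembly, and coordinates were not carried between builds, so regions are given by position and no genes are named. The alternatives tried were the higher scoring 50% of each list, minimum widths of 500 bp and 2000 bp, merging of regions within 100 bp, at least 50% of a region shared, lists of matched covered length, the 6 arms 2L, 2R, 3L, 3R, 4 and X alone, bins of 1000 bp, region numbers instead of bases, the combined list, and each replicate alone.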

Results

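The occupancy of histone H4 was mapped in late Drosophila embryos in 2 ChIP libraries, each called against its own input. Replicate 1 had 15405 enriched regions that covered 40.6 Mb, or 29.0% of the 13 sequences with regions. Replicate 2 had 12952 regions that covered 32.1 Mb, or 23.0%. The combined list had 22525 enriched regions over 59.99 Mb (42.9%) and 14 regions named as depleted. Regions were of similar width in the 3 lists, with medians of 2003 bp in replicate 1, 1962 bp in replicate 2 and 1931 bp in the combined list. The longest region of each replicate list was the same stretch of 2L, from 4479273 to 4514153 in replicate 1 (34881 bp) and from 4479155 to 4513945 in replicate 2 (34791 bp). Neighbouring regions lay close together, with a median gap of 2526 bp in replicate 1 and 3147 bp in replicate 2. Wider regions had higher scores, with a Spearman rho of 0.68 across the regions of replicate 1 and 0.65 across those of replicate 2; regions are not independent replicates.

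The first comparison asked how far the replicates marked the same sequence. They shared 28.0 Mb, which was 69.1% of the bases of replicate 1 and 87.3% of those of replicate 2, so most of the smaller list lay inside the larger one. The Jaccard index (shared bases over all bases covered by either list) was 62.7%. Circular shifts of 1 list gave a mean of 17.1% and a highest value of 25.6% over 100000 permutations (one-sided permutation p = 1e-05, the smallest they can give). By number, 70.8% of the regions of replicate 1 (95% Wilson interval 70.0 to 71.5%) and 88.8% of those of replicate 2 (88.2 to 89.3%) touched a region of the other list. These touching shares were not compared with shifted lists. Wide and closely spaced regions also touch by chance, so 0 is not their baseline. The Jaccard index was lowest on XHet (30.6%), YHet (39.7%), U (42.7%) and 2LHet (44.5%). XHet, YHet and 2LHet held only 12, 7 and 11 regions in replicate 1 and 8, 4 and 9 in replicate 2. Unequal covered length also limits the index: on YHet 43.2% of the bases of replicate 1 and 83.0% of those of replicate 2 were shared. Among the large arms the index was lower on X, with 55.6%, than on 2R (67.1%), 2L (64.2%), 3L (63.8%) or 3R (63.3%). Differences between sequences were not tested. When replicate 1 was reduced to its highest scoring regions of the same covered length as replicate 2, the shared part was 74.8% of either list. Over 10537 pairs of overlapping regions the scores of the 2 replicates had a Pearson r of 0.81 and a Spearman rho of 0.78, again across regions and not across samples.

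The share of a chromosome held in H4-enriched regions differed widely between sequences. Arm 2R had the highest share in both replicates, 42.1% and 34.3% in replicates 1 and 2. Its ratio to the genome was 1.47 as a mean of both, and it passed the rotation test in each (two-sided permutation test, adjusted p = 0.0407 and 0.0296). The rotated shares of 2R had an SD of 6.19 and 5.30 percentage points in replicates 1 and 2. Few rotations of so long an arm are independent, so these p-values rest on few distinct placements. With the higher scoring 50% of each list the ratio of 2R was 1.46, but it no longer passed in replicate 2 (permutation test, adjusted p = 0.0543, unadjusted p = 0.00418), and against the 6 arms alone it passed in neither (0.227 and 0.224). Arm 3R followed with 37.3% and 29.7%, then 3L with 31.2% and 24.6% and 2L with 28.4% and 23.2%; none of these 3 passed the test in both replicates (adjusted p from 0.262 to 0.956). The X chromosome had 24.4% and 17.7%, lower than each large autosomal arm in both replicates, and did not pass the permutation test (adjusted p = 0.471 and 0.429). With the higher scoring 50% of each list this order did not hold: X had 19.6% and 14.5%, above 2L in both replicates (17.4% and 13.8%) and above 3L in replicate 1 (19.3%). Its regions had higher scores than those of the 4 large autosomal arms, with a median of 0.65 against 0.56 in replicate 1 and 0.66 against 0.57 in replicate 2. The combined list gave the same order of these 5 arms by bases, with 57.3% for 2R, 54.5% for 3R, 45.1% for 3L, 42.9% for 2L and 38.0% for X. By region number 3R came first in the combined list, with 199 regions per Mb against 187 on 2R. There 3R passed the permutation test (adjusted p = 0.0164) and 2R did not (0.243). In the replicate lists 2R passed by number in both (0.0282 and 0.0425), and 3R passed in replicate 1 only (0.00494 and 0.159).

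**Figure D1:**
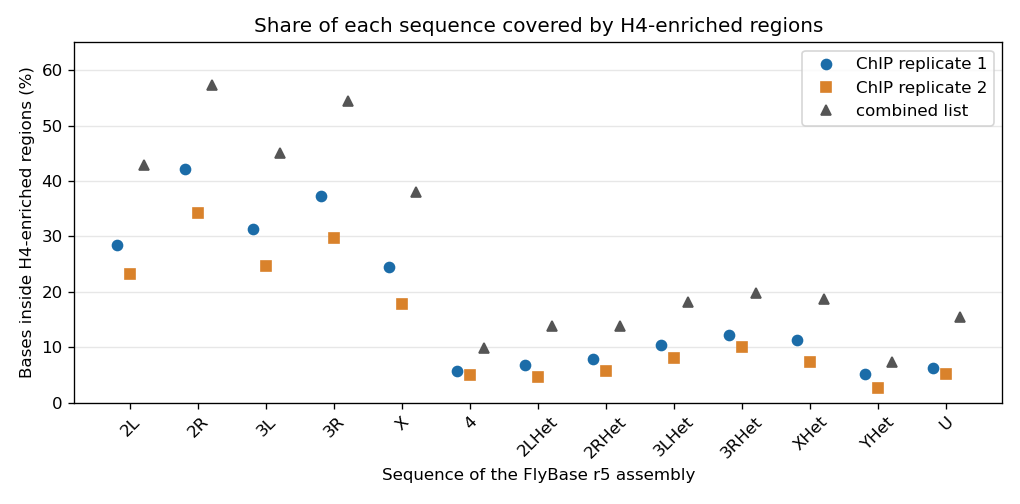
Share of the bases of each sequence (y axis, percent) inside H4-enriched regions, for ChIP replicate 1 (circles), ChIP replicate 2 (squares) and the combined list (triangles); each point is 1 list. The 5 large arms lie between 17.7% and 42.1% in the replicates, while chromosome 4, the Het sequences and U lie between 2.64% and 12.1%.

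Sequences rich in heterochromatin, the compact and repeat-rich part of the genome, held few enriched regions. Chromosome 4, a small and largely heterochromatic chromosome, had 36 regions over 5.75% of its bases in replicate 1 and 32 regions over 5.03% in replicate 2. The Het sequences, which are pericentric scaffolds and those of the Y, were covered to 9.62% and 7.36% as a group. Single values ranged from 2.64% for YHet in replicate 2 to 12.1% for 3RHet in replicate 1. U, a collection of unplaced sequence, was covered to 6.19% and 5.09%, and it was called lower than the genome in both replicates (two-sided permutation test, adjusted p = 0.0407 and 0.0426). U was not called in the combined list, with 15.4% (permutation test, adjusted p = 0.0608), nor with the higher scoring 50% of each replicate list (0.103 and 0.105), where its ratio to the genome was 0.30 against 0.22 for the full lists and its unadjusted p was 0.0239 and 0.0161. Chromosome 4 missed the threshold of the permutation test (adjusted p = 0.262 and 0.238), as did each Het sequence; their short lengths widen the range of rotated values. With the 6 arms as the only background, 4 and X had an unadjusted p under 0.05 in both replicates, but no arm held after adjustment in both. Regions on U had higher scores than those on chromosome 4, with medians of 1.04 and 1.01 in replicates 1 and 2 against 0.49 and 0.53. High scores were not particular to U. The Het sequences as a group had medians of 0.66 and 0.68, against 0.56 and 0.57 on 2L, 2R, 3L and 3R together. YHet had 1.07 and 1.20, from 7 and 4 regions. Whether repeats or mappability shaped the calls and scores on U was not tested.

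Along the arms, the covered share varied strongly and in the same places in both replicates. Over 118 windows of 1 Mb the shares of the replicates had a Pearson r of 0.99 and a Spearman rho of 0.99, across windows, and replicate 1 was above replicate 2 in all 118. The highest window was on 2R from 20000001 to 21000000, near the tip of the arm, with 68.4% and 55.3% of its bases in regions. By the mean of both replicates it was followed by 3L from 1000001 to 2000000 (56.6% and 50.2%), 2R from 19000001 to 20000000 (57.8% and 47.6%), 2R from 3000001 to 4000000 (55.7% and 48.3%) and X from 1000001 to 2000000 (57.9% and 43.6%). By the same mean the lowest windows were the first Mb of chromosome 4 (6.05% and 5.34%), 2L from 17000001 to 18000000 (11.4% and 8.98%) and 3L from 18000001 to 19000000 (12.6% and 10.1%). These windows were chosen after their values were seen.

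**Figure D2:**
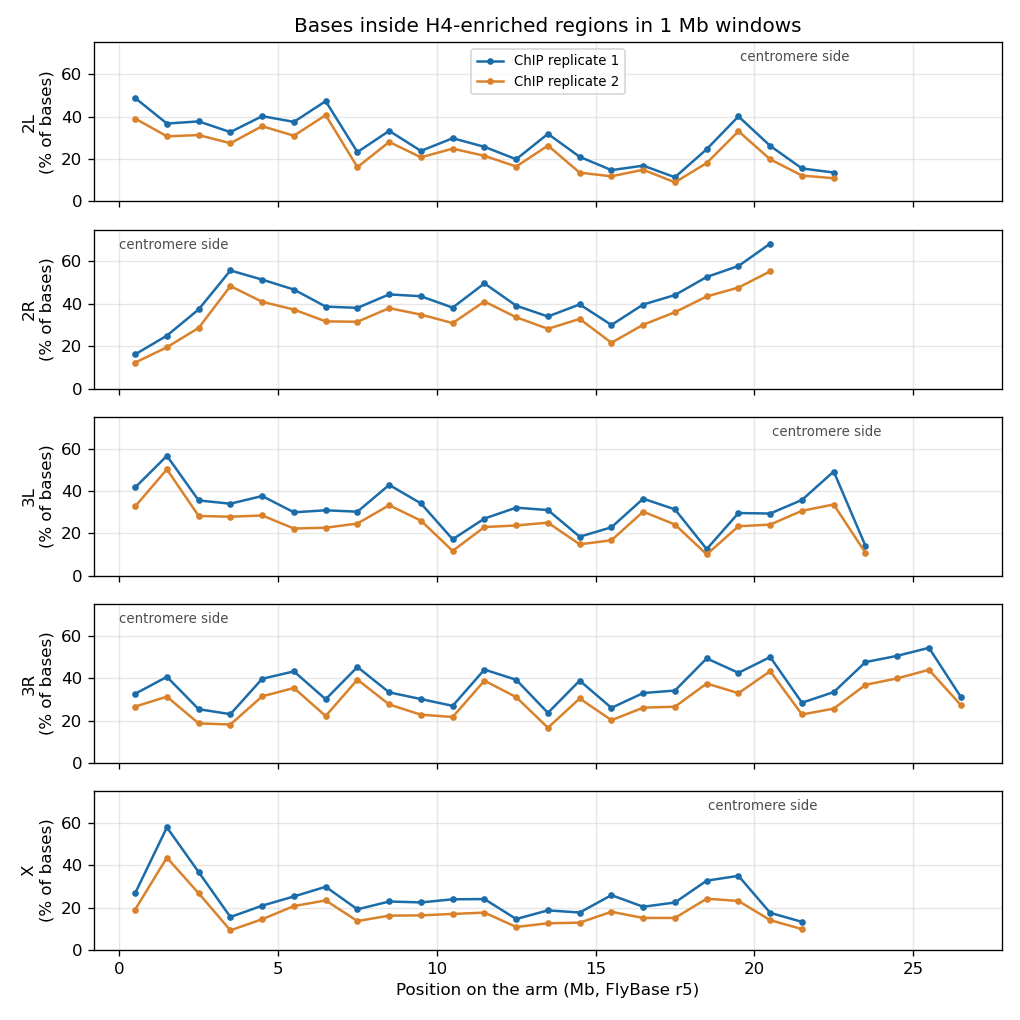
Share of bases inside H4-enriched regions (y axis, percent) in consecutive 1 Mb windows along 2L, 2R, 3L, 3R and X (x axis, Mb in FlyBase r5), for ChIP replicate 1 and ChIP replicate 2; each point is 1 window. Both lines share their peaks and troughs, and replicate 1 lies above replicate 2 in every window.

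The combined list was the next comparison: what it held beyond the lists of single replicates. It took in 99.1% of the bases marked in either replicate. Of its own bases, 46.7% were in both replicate lists, 27.1% were in 1 list and 26.2% (15.7 Mb) were in neither. By number, 9757 regions (43.3%, 95% Wilson interval 42.7 to 44.0%) touched both lists, 5382 touched 1 and 7386 touched neither. Regions found in both were wider, with a median of 3176 bp, than those found in neither, with a median of 1278 bp. The combined list had 4256 regions narrower than any region of the replicate lists. The Wilson intervals treat regions as independent and cover counting error only. How many regions would touch both lists by chance was not computed.

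The 10 longest regions that were at least 50% covered in each replicate were all on the large arms: 3 on 2L, 2 each on 2R, 3L and X, and 1 on 3R. The longest was on 3L from 22295426 to 22340979 (45.6 kb), near the centromere side of that arm, with 98.4% and 93.3% of its bases in the lists of replicates 1 and 2. A further member lay close by, on 3L from 22367193 to 22399466 (32.3 kb, 95.1% and 77.9%). The region on 2L from 4479146 to 4514176 (35.0 kb) had the highest score of the 10, at 0.98, and was 99.6% and 99.3% covered as a single unbroken region in each replicate. The others on 2L spanned 1158411 to 1186010 (27.6 kb) and 6181429 to 6208936 (27.5 kb). On 2R they spanned 18139205 to 18173207 (34.0 kb) and 6580268 to 6605748 (25.5 kb), and on 3R 20461554 to 20487892 (26.3 kb). The pair on X spanned bases from 1379980 to 1410485 (30.5 kb) and from 1475211 to 1503321 (28.1 kb), and replicate 2 covered them less, to 52.8% and 60.8%, than replicate 1, to 86.1% and 85.7%.

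**Figure D3:**
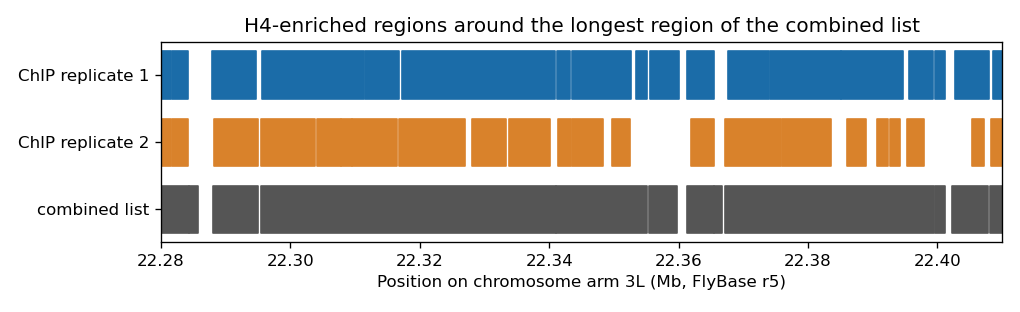
Enriched regions on 3L from 22.28 to 22.41 Mb (x axis, FlyBase r5), drawn to scale as bars for ChIP replicate 1, ChIP replicate 2 and the combined list. The longest region of the combined list, 45.6 kb, corresponds to 3 regions in replicate 1 and 7 in replicate 2, separated by short gaps.

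The 10 highest scoring regions under the same rule were all on U. They were short, from 2004 to 3811 bp, and had scores from 1.62 to 2.39, above the 0.65 to 0.98 of the 10 longest regions. Scores on U were high in general, with a median of 0.96 in the combined list against 0.38 on 2L and 0.45 on X. Without the rule the highest score of the combined list was 3.61. The top region lay on U from 7363321 to 7365324 with a score of 2.39, and 76.1% and 93.7% of its bases were in the lists of replicates 1 and 2. The next were on U from 9205251 to 9208317 (score 2.31) and from 8776872 to 8780682 (score 1.97). No region met both rules. The combined list also had long stretches with no region. Its longest gap on the 6 arms was on chromosome 4 from 222222 to 384392 (162 kb). The next were on 2L from 21413170 to 21542621 (129 kb), on chromosome 4 from 24267 to 142849 (119 kb) and on 2R from 2211201 to 2319698 (108 kb). Neither replicate had a region in 3 of these 4 gaps, and replicate 2 had 1 region in the gap on 2L. The combined list took in 99.1% of the bases marked in either replicate, so this was nearly fixed in advance. The gaps were chosen after their values were seen.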

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

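All tests of the depleted regions, chromosome 4 and the pericentric sequences were chosen after their values were seen, and the test of X before its result but after the higher median score on X had been seen.

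The combined list named 14 regions as depleted of H4, a class outside the comparisons of enriched regions and one that neither replicate list contains. They lay on 2R (6), 3L (5), 3R (2) and 2L (1), were 1389 to 1627 bp wide and had scores from -0.11 to -0.0026. Of the 14, 8 lay inside a region that replicate 1 called enriched and 1 inside an enriched region of replicate 2, with 95.7 to 100% of their bases. Random placement outside the enriched regions of the combined list gave a mean of 0.0731 and at most 2 of 14 for replicate 1 (one-sided permutation p = 1e-04, the smallest that 10000 placements can give). The deepest, on 2R from 11214623 to 11216094, was 97.8% inside a region of replicate 1. A candidate explanation is that weak calls were sorted into enriched or depleted by the sign of a score near 0: the 9 replicate regions that held them were all at or below percentile 0.325 of their own list by score, while the other 5 of the 14 lay in no replicate region and are not covered by this test. Only 39 regions of replicate 1 and 21 of replicate 2 had no overlap with enriched regions of the combined list. Whether regions left out of that list score this low in general was not compared, so the percentiles do not single out this explanation. True depletion in the other replicate stays open, since no signal per replicate was used.

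The X chromosome had less of its length in enriched regions than 2L, 2R, 3L and 3R together, with a ratio of 0.71 (95% interval 0.60 to 0.85) in replicate 1 and 0.64 (0.54 to 0.77) in replicate 2, from a bootstrap of 1 Mb windows, although the rotation test did not call it. In a mixed-sex population X has fewer copies than the autosomes, and fewer reads may raise the score a region needs to be called. Among regions under 1500 bp the 5th percentile of the score was 0.33 on X against 0.23 on these arms in replicate 1 and 0.42 against 0.31 in replicate 2. Among regions above the X median score the ratio was 0.958 as a mean of the replicates, with intervals of 0.77 to 1.21 and 0.75 to 1.22, which leaves room for a lower share too. Part of this rise toward 1 follows from the higher median score on X, and truly higher scores there would give it too, so a raised limit stays a candidate that the test does not separate from a difference in H4 occupancy.

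Chromosome 4 and the pericentric Het sequences were covered far less than 2L, 2R, 3L and 3R, with ratios of 0.15 and 0.16 for chromosome 4 and 0.28 and 0.27 for Het in replicates 1 and 2. The first test asked whether regions under 1500 bp needed a higher score there: on Het their median score was higher by 0.112 as a mean of the replicates (intervals 0.068 to 0.16 and 0.087 to 0.16), while on chromosome 4 the difference of -0.0067 rested on 8 and 4 regions and both intervals included 0. After these results were seen, the test used for X was put in its place, and it gave another answer for Het. Among regions above each group's own median score the mean ratio was 0.392 for Het (intervals 0.29 to 0.44 and 0.34 to 0.52). This argues against a raised score limit as the whole cause there. For chromosome 4 it was 0.114 (0.043 to 0.19 and 0.046 to 0.22), with both intervals wholly under 1. The median score of chromosome 4 was lower than that of the 4 arms (0.49 and 0.53 against 0.56 and 0.57). The cut therefore kept over 50% of the regions of the arms, so the low ratio follows from these medians and the low covered share. A raised limit as the whole cause would leave mainly high scores on chromosome 4. Its medians, from 36 and 32 regions and without an interval, were not high. Together with the ratio this argues against such a limit as the whole cause on chromosome 4. On both Het and chromosome 4 it may still be part of the cause. Unplaceable repeats or a true difference of chromatin stay open for both, since no sequence or mappability was used.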

How the results depend on the processing

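Depth is unknown here, so its effect on the lists was not tested. The minimum width of 2000 bp, the merging of regions and the background of 6 arms were chosen after seeing the data. The planned minimum of 500 bp removed no region and tests nothing. The overlap of the replicates stayed above all shifted lists under each setting tried, with Jaccard indices from 57.0% to 63.3%. With the higher scoring 50% of each list, the mean number of regions was 7090, the mean covered share 16.8%, the shared regions 65.2% of replicate 1 and 81.1% of replicate 2, and 41.2% of the combined regions touched both lists; with widths of at least 2000 bp these were 6977, 17.8%, 69.8%, 91.0% and 47.6%. With at least 50% of a region shared, the values were 66.6% for replicate 1, 86.5% for replicate 2 and 38.3% for the combined list; at matched covered length they were 79.4%, 69.5% and 33.6%, as replicate 1 then held fewer regions. On the 6 arms alone 89.4% of replicate 2 was shared. Pairs sharing at least 50% of both regions had a rho of 0.80. Of the 2 sequence calls, 0 held with the higher scoring 50% (3 at an unadjusted permutation p under 0.05 in both replicates: 2R, 4 and U), and 0 were made against the 6 arms (2 unadjusted: 4 and X). By bases, the combined list called 2R and 3R but not U. Uncalled ratios crossed 1 for 2L with 1 replicate left out (0.976 to 1.01), for 3L against the 6 arms (0.96) and for X with the higher scoring 50% (1.01); the cause was not tested for 2L and 3L, and for X a raised score limit is weighed above. No paired analysis was possible because the input libraries have no values in the files used, so ChIP and input share no numbered pair of measurements.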

Other observations

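The tests in this part were fixed before their results were seen, except where stated, though the width limits used for the combined list were set after region widths had been seen.

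The end of each large arm away from the centromere was the part richest in H4-enriched regions. When 2L, 2R, 3L, 3R and X were each cut into 5 equal parts, the outermost part had the highest covered share on all 5 arms in both replicates, a pattern noticed after the values were seen. In replicate 1 it reached 53.6% on 2R, 46.0% on 3R, 41.3% on 3L, 39.5% on 2L and 32.9% on X. The part at the centromere was the lowest on 2R alone, in both replicates. In replicate 1 the lowest was the part before it on 2L (16.72% against 25.05%) and X (20.9% against 23.5%), and the middle part on 3L (25.5% against 30.1%) and 3R (33.1% against 33.3%); the same parts were lowest in replicate 2.

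The hypothesis that the covered share is lower next to the centromere was tested on the innermost part. It was below the mean of the rest on 5 of 5 arms in both replicates, by 4.40 percentage points in replicate 1 (one-sided permutation p = 0.0423 over 100000 joint shifts) and 3.94 in replicate 2 (p = 0.0332), a mean of 4.17. The rest included the outermost part, the highest on all 5 arms, so the outer end adds to the difference. The difference does not show a steady fall along the arms. On 3L and X the innermost part was above both the middle part and the one next to it in each replicate. In the combined list X was the exception, with 38.5% in the innermost part against 37.9%. The sequence at this end is richer in repeats, so fewer usable reads may contribute.

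A further hypothesis was that regions gather in domains wider than single regions. The SD of the covered share over 100 kb windows was 16.2 percentage points in replicate 1 and 14.7 in replicate 2, a mean of 15.4. In 1000 lists with gaps and widths shuffled within each arm the highest values were 10.8 and 10.4, so none was as large in either replicate. This is consistent with clusters wider than single regions, of a size that was not tested, since no other window was used. The shuffles do not separate chromatin from uneven input or mappability.

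Regions of the combined list that touched neither replicate list were examined for what set them apart. If narrower calls alone were the reason, most of their bases would lie in regions narrower than any replicate region, and 44.9% did; by number 4013 of the 7386 regions were that narrow. The other bases lay in regions as wide as replicate regions, so narrower calls cannot be the only reason, while their part in it stays open. Over all widths their median score was lower, 0.355 against 0.513 for regions that touched both lists, but they were also narrower, and narrower regions score lower. Regions that touched 1 list had a median score of 0.353, although they were wider (median 1796.5 bp against 1278 bp). If regions found in neither list were weaker than those found in both, their scores would be lower at equal width. Among wider regions of up to 2000 bp the median score was 0.33 both for the 2904 found in neither list and for the 1514 found in both, a difference of -0.00475 (95% interval -0.011 to 0.0022), so a lower score at equal width was not shown. More reads in the combined call may also matter, which could not be tested without depth.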
